A study of Homo sapiens with 6 samples.

How the data were processed

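RNA sequencing was carried out on HG3, a lymphoblastoid cell line established from the B cells of a patient with chronic lymphocytic leukaemia. Per the labels, 6 libraries of total RNA were measured: 3 from control pools and 3 from fludarabine-resistant pools, numbered 17, 18 and 28 in both groups. Fludarabine is a purine nucleoside analogue that has to be phosphorylated inside the cell before it acts. Per the labels' protocols, total RNA was extracted with an RNeasy Plus Mini kit and its integrity was examined on a Bioanalyzer. How RNA was selected for the libraries, whether strand was kept, and the read length are not given in the sources used here.

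The values deposited by the authors were FPKM, fragments scaled by transcript length and by the mapped fragments of the library, per the file headers. Each file gave 1 value for each of 23619 gene symbols, written with decimal commas. Per the submitters' processing notes, TopHat2 2.0.4, Cufflinks 2.2.1, HTSeq 0.6.1 and DESeq2 were used with the build hg19; the step each tool served, and the annotation, are not given in the sources used here. The FPKM were used as deposited, without counts, so no count model was fitted. No value was negative or unreadable, no symbol was blank or repeated, and 0 rows were mitochondrially encoded transcripts. Genes of microRNAs and other small RNAs are far shorter than a sequencing fragment, and dividing by their length inflates FPKM: 78.7% to 83.4% of each library's sum of FPKM came from them. That sum, 3.38e+06 to 4.89e+06, was therefore not read as depth.

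Relative depth was taken from low values, where a gene's FPKM moves in steps of whole fragments. Taking control 17 as 1, relative depth was 1.03 in control 18, 1.25 in control 28, 1.05 in resistant 17, 1.09 in resistant 18 and 1.31 in resistant 28. Between 69.8% and 73.4% of the ratios of low values were then ratios of small whole numbers, within a tolerance of 0.02 on the log2 scale, against 20.0% by chance. Absolute depth was not estimated, and no counting interval was computed for a gene.

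Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, 11307 in all. The difference between resistant and control libraries was estimated on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The pseudocount of 1 shrinks the differences of genes with low FPKM. Folds are ratios of mean FPKM and errors are standard deviations over 3 libraries unless a standard error is named. The labels do not say whether the pools were separate from the start of selection, so p-values measure the spread between these libraries.

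The design text speaks of 3 pairs of pools, and each number occurs once in each group, so libraries with the same number were treated as pairs. Their deviations from the group means correlated across genes at 0.148 for pool 17, 0.0892 for pool 18 and -0.0243 for pool 28, so the numbers marked little shared variation. The reported fit had no block for the pool, and the fit with the pool number as a block was an alternative, given beside a result where it changed the call.

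A total of 30 gene lists were fixed before the data were examined: drug handling, apoptosis, p53 and DNA repair, MAPK signalling, proliferation, B cell identity, metabolism and stress, interferon, chromatin, markers of other cell types, and signs of RNA quality. Of these, 28 had at least 3 tested genes and were tested with limma's camera, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Each was also tested with an estimated correlation and with fry, which tests whether a list's genes move one way on balance. Both were run on all 6 libraries only, so they do not test a call made with a library or pool left out. Genes were named by rules fixed at the same time. Up to 12 genes per direction were named if they passed the threshold and moved alike in all 3 pools, and places left over went to the smallest unadjusted p among genes moving alike. DCK, BMP2K, ARID5B and BRAF were named whatever their result, with up to 4 passing members of each list or otherwise the 2 of smallest p. For each pool, the 3 largest differences in each direction that stayed under 0.5 in the other pools were named. Any other gene named was chosen after its values were seen, and 1 gene that the rules named is not reported here.

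GC content and transcript length came from the protein-coding transcripts of GENCODE v29 (GRCh38) and were matched by symbol for 9919 tested genes, 87.7%. For a fit with these trends removed, a loess surface of span 0.5 over GC content and log2 length was fitted to each library's deviations from the gene means and subtracted. The order of genes along chromosomes came from RefSeq on GRCh38.p14. Because the authors' build was hg19, no coordinates are given. Alternatives were another pseudocount (0.1 or 5), no filter or a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, the pool block, no mean-variance trend, array weights, and leaving out each library and each pool. With a library left out the filter asked for an FPKM of at least 1 in 3 of the 5 left, and fewer genes were tested (11131 to 11211). With a pool left out it asked for this in 2 of the 4 left, and more genes were tested (11331 to 11455). Small RNA genes left out, the libraries and pools left out with the same 11307 genes tested, and GC and length trends removed with and without the block, were added after the data were seen.

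The procedure was tested on simulated data for this comparison: 200 of the 11307 genes were changed in each of 5 runs with each gene's own residual spread. It recovered 41.2%, 82.4% and 89.4% of genes changed by 1, 2 and 3 on the log2 scale, with 0 calls of the wrong sign and 31 false calls over all runs. Camera called a shifted list in 5 of 5 runs and an unshifted list in 0, at an unadjusted p under 0.05. Genes were simulated independently of each other, so these runs do not test camera on lists whose genes move together. Values were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.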

Results

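The transcriptomes of 3 control pools and 3 fludarabine-resistant pools of HG3 cells were compared, with 1 library per pool and group. Between 10936 and 11331 genes per library reached an FPKM of 1. Relative depth ranged from 1 in control 17 to 1.31 in resistant 28. The design asked whether resistant cells differed from their parental cells across the transcriptome. The pools came from a transposon mutagenesis study, in which insertions of a mobile element alter genes at random before drug selection.

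BIN1 and HBE1 fell in the resistant pools. BIN1, which encodes a membrane-bending adaptor protein that also binds MYC, had 29.8 ± 2.29 FPKM in controls and 4.36 ± 0.372 in resistant libraries (SD, n = 3 each), 6.83-fold lower. Its log2 difference was -2.52 (SE 0.15, limma adjusted p = 0.00166), and it lay between -2.62 and -2.44 in each pool. HBE1, the embryonic epsilon-globin gene, had 24.0 ± 3.76 FPKM in controls and 3.31 ± 0.918 in resistant libraries, with a log2 difference of -2.54 (SE 0.21, adjusted p = 0.0147). MIR744 and RNU6-28, a microRNA gene and a copy of the U6 small nuclear RNA, also passed, and were listed at 0 in all 3 controls. MIR744 had 116, 89.4 and 74.4 FPKM in resistant 17, 18 and 28, and RNU6-28 had 29.8, 28.7 and 36.8. The values of MIR744 times relative depth were 5, 4 and 4 times a smallest step.

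A total of 4 of 11307 genes passed limma's adjusted threshold, 2 higher and 2 lower in resistant libraries, and 1484 had an unadjusted p under 0.05 (677 higher and 807 lower, 565 expected by chance). This unadjusted count depended on single libraries and pools. It ran from 567 without pool 28 to 2623 without resistant 18, with the filter scaled to the libraries left. With the pool as a block 3 genes passed, and HBE1 did not (adjusted p = 0.152). With GC and length trends removed and the block, 0 of 9919 genes passed in limma, and 1454 had an unadjusted p under 0.05. Those 9919 genes, matched for GC content and length, did not include MIR744 and RNU6-28. BIN1 had an adjusted p of 0.0733 in that fit, although the log2 differences of BIN1 (-2.51) and HBE1 (-2.56) hardly moved. HBE1 missed the threshold without a filter on low values (0.0940), without control 17, control 18 or control 28 (adjusted p = 0.0507, 0.152 and 0.144) or without pool 28 (0.217), and BIN1 did without pool 17 or pool 28 (0.0535 and 0.0882). MIR744 and RNU6-28 did not reach the filter, and were not tested, when a resistant library was left out alone, and passed there when the same 11307 genes were tested. They are among the 11307 only because all 3 resistant libraries, the one left out included, reached the minimum, so passing there is no further support. With the same 11307 genes tested, 13 passed without resistant 18, 18 without pool 18 and 8 without resistant 17. HBE1 was not among those without pool 17, pool 18 or pool 28. With a filter scaled to the libraries left, 5 passed without resistant 18 and 58 without pool 18, where genes above the minimum in 2 libraries were also tested. With array weights, which gave resistant 18 a weight of 0.162 and the other libraries 1.03 to 1.93, 301 genes passed.

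The genes next in rank missed the threshold and moved alike in all 3 pools, and each passed with array weights. Among those with lower values in resistant libraries, the histone H3 gene HIST1H3C had 1156 ± 201 FPKM in controls and 20.4, 8.86 and 0.776 in resistant 17, 18 and 28 (log2 difference -7.31, adjusted p = 0.0656). It passed with a pseudocount of 5 (adjusted p = 0.00662), without resistant 17 (0.0136), without resistant 28 (0.00499) and without pool 28 (0.0274). SON, a splicing cofactor, had 47.2 ± 11.1 against 12.7 ± 0.623 FPKM, and USP14, a deubiquitinase of the proteasome, 22.9 ± 4.06 against 7.04 ± 0.525 (both adjusted p = 0.0656), and both passed with GC and length trends removed (0.0434). POLR2A, the largest subunit of RNA polymerase II, differed by -1.92 (adjusted p = 0.136), PCBP1 by -1.60, ADNP by -1.52, the mitochondrial aldehyde dehydrogenase gene ALDH2 by -1.46, the phosphatase gene PTP4A1 by -1.34 and the chromatin-remodelling gene GATAD2B by -1.11. OR51B5, an olfactory receptor gene beside the beta-globin cluster, differed by -1.34 (adjusted p = 0.132), and passed without pool 18 (0.0404), though not with the same 11307 genes tested, where it passed without resistant 18.

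Among those with higher values, MBD2, which encodes a protein that binds methylated DNA, had 27.1 ± 2.45 FPKM in controls and 59.6 ± 2.32 in resistant libraries (log2 difference 1.11, adjusted p = 0.135). The ribosomal protein gene RPS16 had 266 ± 122 against 1321 ± 204 FPKM (2.39, adjusted p = 0.135). The log2 difference was 1.70 for ACSS3, 1.49 for CCDC73, 1.38 for ERICH1, 1.34 for the B cell gene FCRLA, 1.12 for the adaptor gene DOK1, 1.03 for BANF1, whose protein binds DNA at the nuclear envelope, and 1.02 for ZCCHC3 (adjusted p from 0.135 to 0.158).

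**Figure D1:**
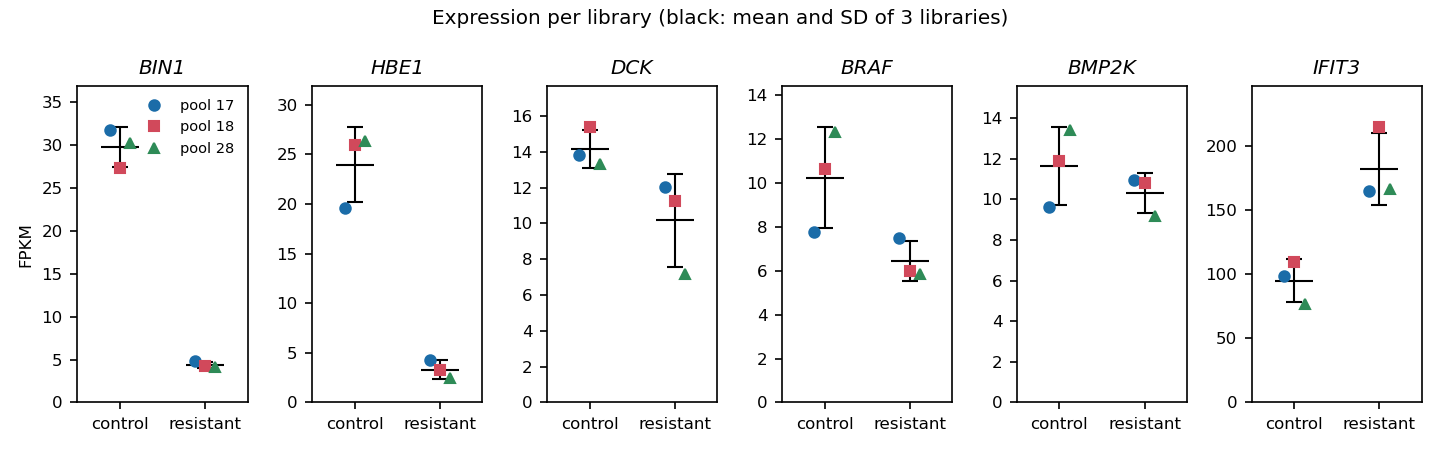
FPKM of 6 genes in each library, with pools marked by colour and shape, and mean and SD of the 3 libraries of a group in black. BIN1 and HBE1 have 4.09 to 4.79 and 2.44 to 4.27 FPKM in resistant libraries, below every control, while DCK, BRAF, BMP2K and IFIT3 did not pass the threshold.

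Differences from control were more alike in pools 17 and 28 than in pool 18 and either of them. The differences between resistant and control libraries correlated across the 11307 tested genes at a Pearson r of 0.49 between pools 17 and 28 (Spearman 0.52), but at 0.01 between pools 17 and 18 (Spearman 0.08) and at 0.11 between pools 18 and 28 (Spearman 0.16). Genes are not independent replicates, so no p is given. Pool 18 had 1431 genes that differed by over 1 on the log2 scale, against 914 in pool 28 and 472 in pool 17. The same direction in all 3 pools was seen for 37.6% of genes, against 25% by chance. The first principal component, with 41.4% of the variance, set resistant 18 (58.8) apart from the other 5 libraries (-33.5 to 6.8). The second, with 29.3%, separated the controls (12.8 to 35.2) from the resistant libraries (-29.2 to -21.6).

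**Figure D2:**
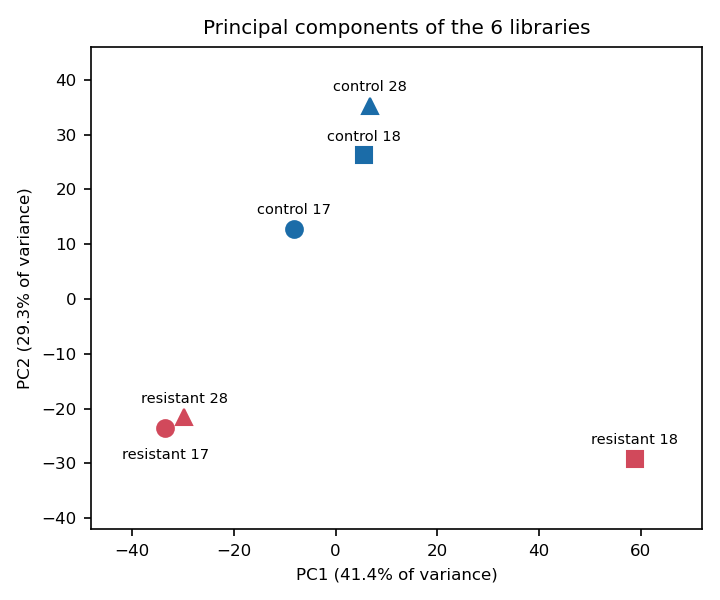
Principal components of log2(FPKM + 1) over the 11307 tested genes, with 1 point per library, blue for control and red for resistant. Resistant 18 lies at 58.8 on the first component, and the controls lie above 0 and the resistant libraries below 0 on the second.

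DCK, the kinase that adds the first phosphate to fludarabine, was the gene of most direct interest. It had 13.8, 15.4 and 13.3 FPKM in controls 17, 18 and 28, and 12.1, 11.3 and 7.20 in the resistant libraries of the same pools. The log2 difference was -0.18 in pool 17, -0.42 in pool 18 and -0.81 in pool 28, and -0.47 over the pools (SE 0.21), which did not pass (limma adjusted p = 0.399). The kinase gene BRAF differed by -0.05, -0.74 and -0.96 in pools 17, 18 and 28, with -0.58 over the pools (SE 0.20, adjusted p = 0.30). BMP2K, another kinase gene, had 11.6 ± 1.91 FPKM in controls and 10.3 ± 0.989 in resistant libraries (adjusted p = 0.748). The chromatin gene ARID5B lay between 0.239 and 0.784 FPKM in all 6 libraries and was not tested. These 4 genes were followed in the study of these cells and are no independent evidence. As a list, the 3 tested ones did not pass (camera adjusted p = 0.0976, 0 genes adjusted over the list alone), but did without resistant 17 (0.0461) or pool 17 (0.0281). With an estimated correlation over all 6 libraries its adjusted p was 0.872.

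The tested genes on both sides of DCK had lower values in resistant 28, and in resistant 18 those on the side that holds BMP2K did. With GC and length trends removed, the median difference of the 41 consecutive genes centred on DCK, from SRD5A3 to PAQR3, was -0.06 in pool 17, -0.39 in pool 18 and -0.68 in pool 28. Between controls it was 0.03 to 0.07. In pool 28, 17 of the 20 genes before DCK and 20 of the 20 after it were below the median of all genes (medians -0.80 and -0.60). In pool 18, 10 of the 20 before DCK and 20 of the 20 after it were (0.03 and -0.73), and the lowest windows of 41 genes were centred on CCNI to MRPL1 (-0.57). The window was chosen after the data were seen, and neighbouring genes are not independent. Other long regions differed with the trends removed. Each was a run of at least 15 windows of 41 genes whose medians lay at least 0.3 from 0. Regions are named by the genes at the centre of the first and last window, with the median of the genes from one to the other. In pool 18, KAT2A to PHB (0.43), CENPV to SLC46A1 (0.38), WIPI1 to CASKIN2 (0.37) and C1QTNF1 to ASPSCR1 (0.59) were higher. So were SMOX to JAG1 (0.50) and NTN1 to NCOR1 (0.34). In pool 18, ZNF706 to ENY2 met the rule for a lower region through its windows, but the genes from one to the other hardly differed (-0.06, 9 of 15 lower). Lower in pool 18 were SGCZ to DOK2 (-0.39) and SLC20A2 to ZBTB10 (-0.42). There, over CYP7B1 to PAG1, control 18 was also above control 17 (0.34). The region that held DCK in pool 18, POLR2B to MRPS18C, had -0.49. In pool 28, CD276 to AKAP13 was higher (0.53) and the histone gene region HIST1H3C to HIST1H2BM lower (-0.38). Over histone genes there control 18 was also above control 17 (0.37) and control 28 below control 18 (-0.37).

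**Figure D3:**
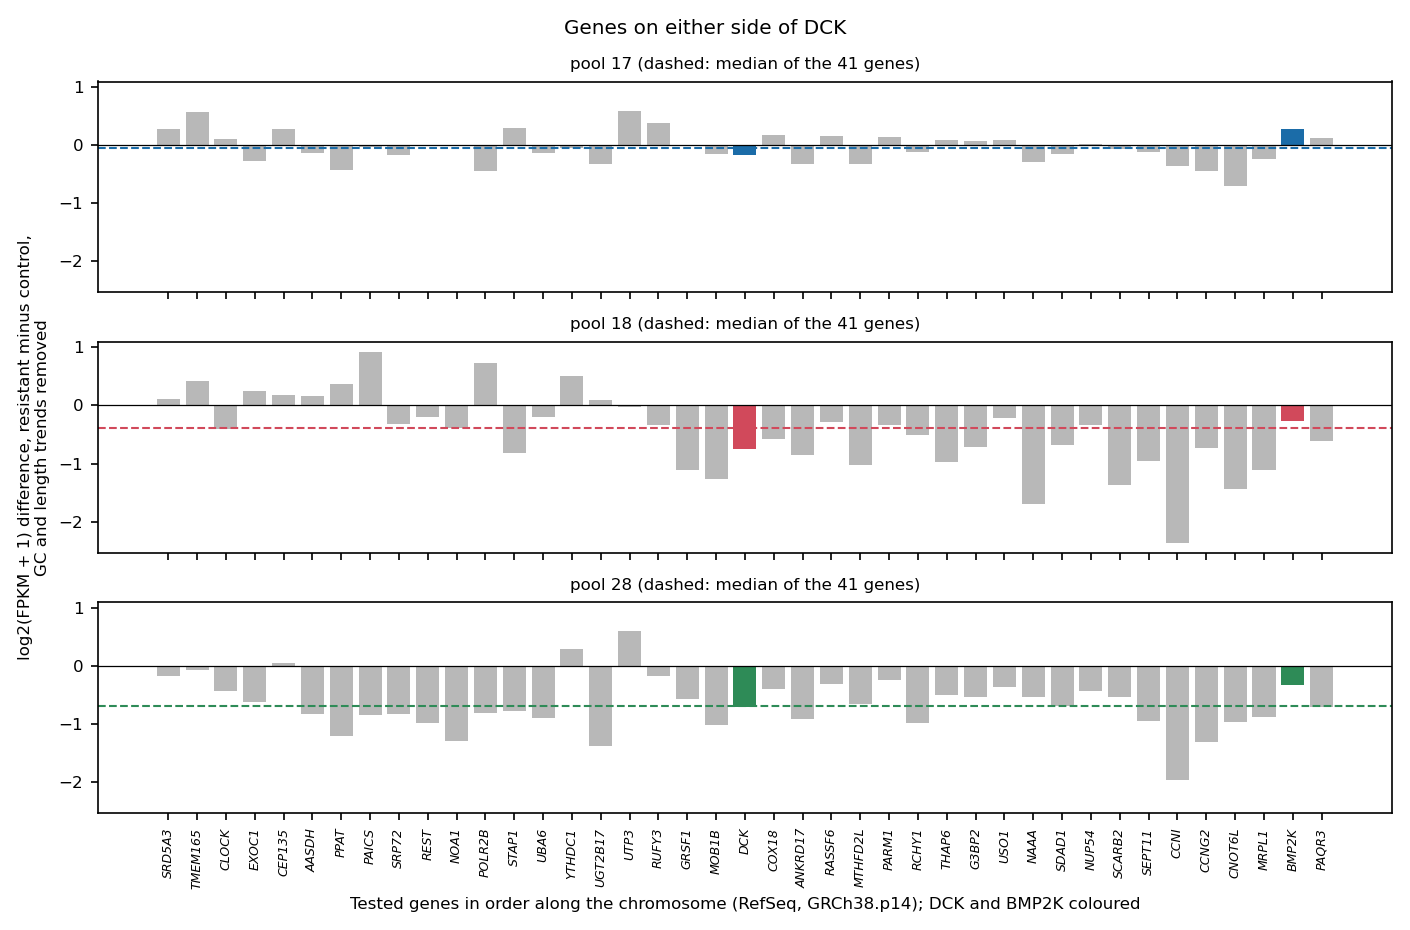
Difference between the resistant and the control library of each pool for the 41 tested genes centred on DCK, in chromosome order, with GC and length trends removed and the median of all genes set to 0. Dashed lines give the median of the 41 genes, -0.06, -0.39 and -0.68 in pools 17, 18 and 28.

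The lists of nucleoside handling did not pass. Among 12 tested genes of nucleoside uptake and activation, DCK included, 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.846). NME4, a nucleoside diphosphate kinase gene, differed by 0.35 (SE 0.18, adjusted p = 0.454). Among 21 genes of nucleotide breakdown, dNTP supply and drug export, 0 passed either way (camera adjusted p = 0.846). The export pump gene ABCC1 differed by -0.63 (adjusted p = 0.272) and the deaminase gene DCTD by -0.39 (0.360).

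Genes that protect from apoptosis included BCL2A1, with 121 ± 8.34 FPKM in controls and 219 ± 35.6 in resistant libraries (log2 difference 0.84), and MCL1, with 27.8 ± 3.19 against 42.2 ± 3.38 (0.59). Both passed adjusted over the list alone but not over all genes (adjusted p = 0.184 and 0.226). Of the 11 anti-apoptotic genes, 5 were higher in all 3 pools and 1 was lower. The list missed the threshold (camera adjusted p = 0.0722), and passed without a filter (0.0412), with GC and length trends removed (0.0221), and without control 28 (0.0453), resistant 28 (0.0490) or pool 28 (0.0458). With an estimated correlation over all 6 libraries its adjusted p was 0.590. The 18 pro-apoptotic genes had 0 that passed either way (camera adjusted p = 0.783), with PMAIP1 at 0.40 and BMF at -0.39. Among 29 targets of p53, 0 passed either way (0.721), with ZMAT3 at -0.90 and PHLDA3 at 0.97. Among 45 genes of DNA repair and damage checkpoints 0 passed either way (0.451), with the base excision repair gene APEX1 at 1.12 and ERCC5 at -0.46. The DNA repair list had medians of -0.04, 0.47 and -0.20 in pools 17, 18 and 28. It passed, upward, without resistant 28 (0.0145) or pool 28 (0.0154), and turned downward without resistant 18 (0.157) or pool 18 (0.289), where it did not pass. Its adjusted p with an estimated correlation over all 6 libraries was 0.872.

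In the MAPK pathway, 0 of 38 component genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.758), with MAP2K3 at -1.01 (SE 0.24, adjusted p = 0.197) and MAPK11 at 0.68. ERK target and feedback genes had 0 of 18 that passed either way (0.542), with the phosphatase gene DUSP4 at -0.63 and SPRED2 at -0.49. Their median was 0.41 in pool 17, -0.47 in pool 18 and -0.19 in pool 28, and the list passed, downward, without resistant 17 (0.0211) or pool 17 (0.0281), and turned upward without resistant 18 (0.613) or pool 18 (0.882), where it did not pass. Its adjusted p with an estimated correlation over all 6 libraries was 0.872.

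The interferon response list rose as a group. Of its 29 tested genes, 28 had a positive difference and 13 were higher in all 3 pools, with a median of 0.46 (camera adjusted p = 3.72e-07). With an estimated correlation of 0.19 the adjusted p was 0.590, and with fry it was 0.208. The median was 0.50 in pool 17, -0.01 in pool 18 and 0.76 in pool 28. IFI35 had 20.9 ± 5.38 FPKM in controls and 52.3 ± 7.64 in resistant libraries (1.31, SE 0.23), and the antiviral gene IFIT3 94.96 ± 16.7 against 182 ± 28.1 (0.94, SE 0.21). Both passed adjusted over the list alone and neither did over all genes (adjusted p = 0.158 and 0.183).

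Histone and chromatin regulators fell as a group, with a median of -0.45 over 25 tested genes, 15 of them lower in all 3 pools and 4 higher (camera adjusted p = 1.2e-04). With an estimated correlation the adjusted p was 0.590, with fry 0.119, and among genes with a mean FPKM of at least 5 it was 0.152. Adjusted over the list alone 9 genes passed, all lower, and over all genes 0 did. The histone methyltransferase gene MLL had 6.33 ± 1.89 FPKM in controls and 2.10 ± 0.219 in resistant libraries (-1.21, SE 0.21, adjusted p = 0.158), and the acetyltransferase gene EP300 had 6.16 ± 1.74 against 2.15 ± 0.278 (-1.16, adjusted p = 0.159). The list's median relative to all genes was -0.33, -0.37 and -0.65 in pools 17, 18 and 28, and -0.13, -0.27 and -0.44 for its 22 matched genes once GC and length trends were removed (camera adjusted p = 0.0221).

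Ribosomal protein genes passed downward as a list, with a median of -0.35 over 31 genes (camera adjusted p = 0.00452), 0 of which passed over all genes or adjusted over the list alone. The estimated correlation between them was 0.59, and the adjusted p was 0.872 with it and 0.864 with fry. Their median was -0.97 in pool 18, -0.12 in pool 17 and 0.08 in pool 28. The call was lost without resistant 18 (adjusted p = 0.613), control 18 (0.0557) or pool 18 (0.983), and under quantile normalization (0.223). RPL27 had 1954 ± 272 FPKM in controls and 946 ± 86.8 in resistant libraries, and RPS15 1851 ± 189 against 1028 ± 319.

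Proliferation genes had medians of opposite sign in pools 18 and 28, a difference between pools that was not tested. The 32 genes of S phase and replication had medians of -0.13, 0.82 and -0.37 in pools 17, 18 and 28, and the 30 genes of G2 and mitosis had -0.11, 0.89 and -0.42. Neither list passed (camera adjusted p = 0.721 and 0.666). Without resistant 18 both passed downward (0.00297 and 0.00403), as without pool 18 (0.0191 and 0.0175). Without resistant 28 both passed upward (0.00443 and 3.41e-04), as without pool 28 (0.0103 and 9.37e-04). These calls were made at the preset correlation, and no estimated correlation was run with a library or pool left out. Over all 6 libraries the estimated correlations were 0.770 and 0.908, far above the preset one. The camera adjusted p with them was 0.872 for both lists, which had not passed there at the preset correlation either. Whether the calls would hold with an estimated correlation was therefore not tested. TYMS, the thymidylate synthase gene, was lower in all 3 pools (62.0 ± 14.9 against 23.4 ± 2.99 FPKM, -1.34) and passed adjusted over the list alone, but not over all genes (adjusted p = 0.158). CDT1 differed by -0.64, the proliferation marker MKI67 by -0.91 (adjusted p = 0.182) and NEK2 by 0.45. Within pool 18, MKI67 (-0.90), TYMS (-1.83) and CDT1 (-0.57) were lower. There 30 of the 32 S phase genes and 29 of the 30 G2 and mitosis genes were above the median of all genes.

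**Figure D4:**
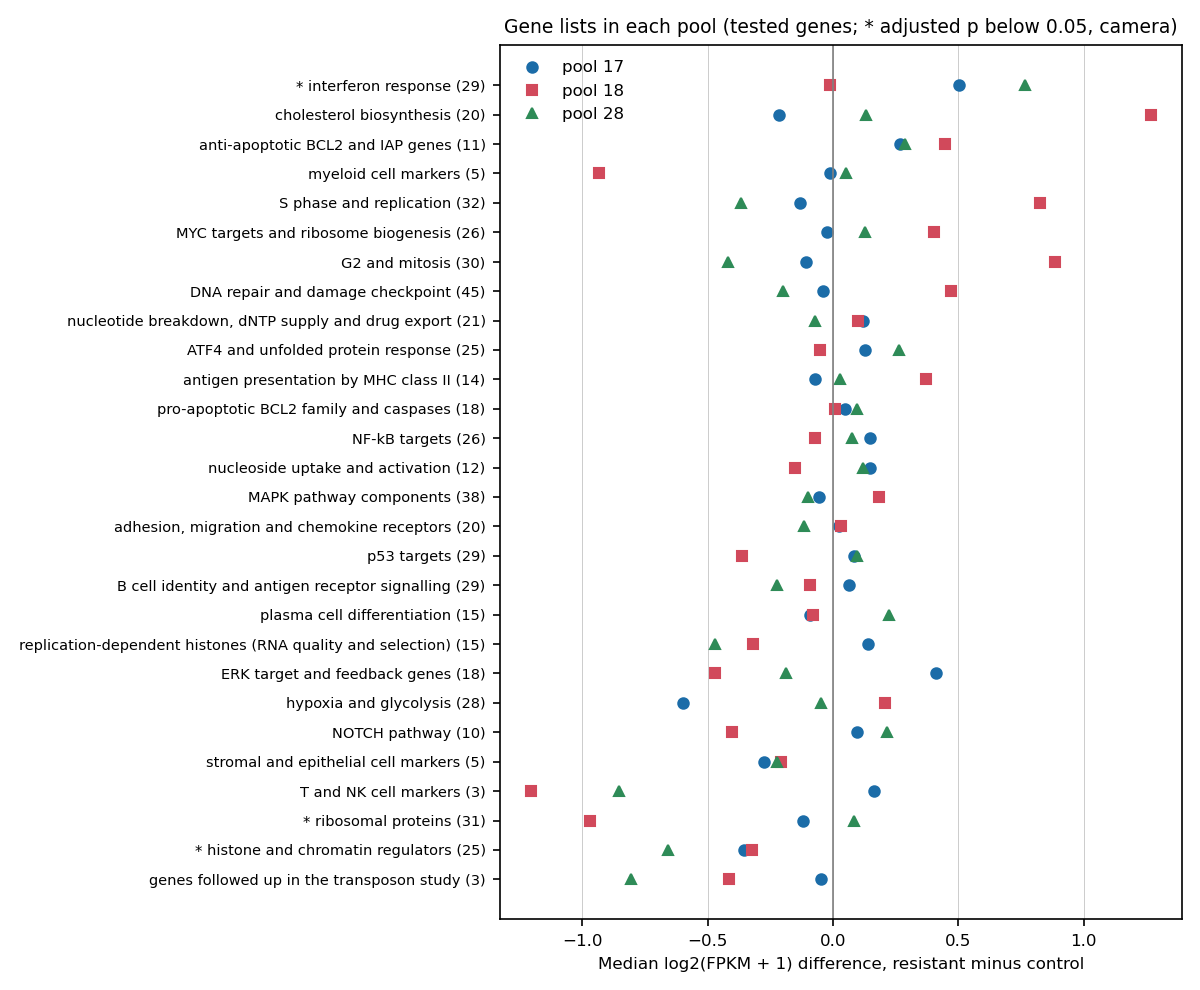
Median difference on the log2(FPKM + 1) scale of each tested gene list in pools 17, 18 and 28, with the number of tested genes in brackets and an asterisk at the 3 lists that passed with camera. Pool 18 stands apart from the other pools for G2 and mitosis (0.89) and for ribosomal proteins (-0.97).

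Lists of B cell biology did not pass. Among 29 genes of B cell identity and antigen receptor signalling, FCRLA passed adjusted over the list alone (5.70, 9.46 and 8.46 FPKM in resistant libraries against 2.13, 2.28 and 2.98 in controls), 9 genes were lower in all 3 pools and 2 higher (camera adjusted p = 0.721). CD81 differed by -0.91. For plasma cell differentiation (15 genes, 0.846), PIM2 differed by -0.48 and MZB1 by 0.63. For NF-kB targets (26 genes, 0.825), the chemokine gene CCL22 differed by -1.28. For antigen presentation by MHC class II (14 genes, 0.460), HLA-DRB1 differed by 0.64 and HLA-DQB1 by 0.41. For the NOTCH pathway (10 genes, 0.542), HEY2 differed by 0.49 and MAML1 by -0.35. In these lists 0 genes passed over all genes. Among 20 genes of adhesion, migration and chemokine receptors (0.758), CD9 (-1.37) and CD44 (-1.24) passed adjusted over the list alone, and not over all genes (adjusted p = 0.182 and 0.192).

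Metabolic and growth lists did not pass. Cholesterol biosynthesis genes had a median of 1.27 in pool 18, -0.22 in pool 17 and 0.13 in pool 28 (20 genes, camera adjusted p = 0.0722), with MVD at 0.63 and NSDHL at 0.47. Hypoxia and glycolysis genes had medians of -0.60 in pool 17, 0.21 in pool 18 and -0.05 in pool 28 (28 genes, 0.0722). The neuronal enolase gene ENO2, with 45.4 ± 8.14 FPKM in controls and 21.4 ± 2.04 in resistant libraries (-1.04), passed adjusted over that list alone, and the glucose transporter gene SLC2A3 differed by -0.53. The cholesterol list passed upward without control 17 (0.0380), control 28 (0.0453), resistant 17 (2.65e-04), resistant 28 (0.0169), pool 17 (2.58e-04) or pool 28 (0.0122), and turned downward without resistant 18 (0.772) or pool 18 (0.420), where it did not pass. With the estimated correlation of 0.669 over all 6 libraries its adjusted p was 0.872. The hypoxia list passed downward without a filter (0.0336), at a mean FPKM of at least 5 (0.0441), and without control 18 (0.00980), control 28 (9.5e-04), resistant 18 (0.0130), pool 18 (0.00171) or pool 28 (0.0347), and with the estimated correlation of 0.475 over all 6 libraries its adjusted p was 0.872. MYC targets and ribosome biogenesis genes (26 genes, 0.0925) had PPAN at 0.99 and SRM at -0.99, and passed upward without control 17 (0.0380), resistant 17 (0.0397), resistant 28 (0.0169), pool 17 (0.0147) or pool 28 (0.0458), with an adjusted p of 0.872 with an estimated correlation over all 6 libraries. For ATF4 and the unfolded protein response (25 genes, 0.758), SDF2L1 differed by 0.73 and VLDLR by -0.68.

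Markers of other cell types were few. Of the marker lists, 3 T and NK cell genes, 5 myeloid genes and 5 stromal or epithelial genes reached the filter, and the lists did not pass (camera adjusted p = 0.542, 0.846 and 0.721). The myeloid list had a positive median (0.19) and a negative mean (-0.16) and test. ZAP70 had 19.3, 36.5 and 25.8 FPKM in controls 17, 18 and 28 and 23.6, 3.83 and 4.49 in the resistant libraries, LAT differed by -0.34, and the T and NK list passed downward without resistant 17 (0.0421). CD33 differed by -1.90 (adjusted over the list alone, it passed), ITGAM by 0.33, CDH1 by 0.66 and KRT18 by -0.72. Of 13 erythroid and platelet markers, HBG2 was tested, at -1.64 (adjusted p = 0.158). Replication-dependent histones, which lack long poly(A) tails, had medians of 0.14, -0.32 and -0.47 in pools 17, 18 and 28 (15 genes, 0.176), with HIST1H2BK at -0.83 and HIST2H4A at -0.56, and passed downward without resistant 17 (0.0397) or pool 17 (0.0281). With an estimated correlation over all 6 libraries the adjusted p was 0.872 for this list and for the T and NK list. Mitochondrially encoded transcripts were not analysed here.

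Genes that moved in a pool alone were, by the rule of size, small RNA genes and a ribosomal protein pseudogene. In pool 17, RNU6-6 (8081 FPKM), MIR378C (265) and MIR296 (230) were above 0 in resistant 17 and listed at 0 in the other 5 libraries, while SNORD115-48 (176) and MIR367 (172) were above 0 in control 17, and MIR4515 (142) there and in both libraries of pool 28. In pool 18, RPL21P28 had 1993 FPKM in resistant 18 and at most 0.0254 elsewhere, SNORD77 (111) and MIR126 (108) were above 0 in resistant 18, and MIR4284 (137), MIRLET7A2 (137) and MIR1538 (122) in control 18. In pool 28, MIR1292 (283), MIRLET7F2 (163) and MIR383 (150) were above 0 in resistant 28, and MIR3653 (39.4) and MIR3190 (38.7) in control 28. MIR1204 had 352 FPKM in control 28, 0 in resistant 28, and 90.3 and 83.9 in control 17 and resistant 17. No test was made for a pool alone.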

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

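Small RNA genes left out, the fits with GC and length trends removed and those with the same genes tested were chosen after the data were seen. The number of genes passing was 301 with array weights, 7 at an adjusted p under 0.1, 2 with small RNA genes left out (the other 2 being small RNA genes), 0 in limma with GC and length trends removed and the replicate block (1454 at an unadjusted p under 0.05), and between 3 and 58 with a library or a pool left out and the filter scaled to those left, which also tested genes seen in 2 libraries when a pool was left out. With the same 11307 genes tested it was 8 without resistant 17, 13 without resistant 18, 18 without pool 18, and 3 to 6 without another library or pool. Under the other settings named in the methods 3 to 6 genes passed. The fits with GC and length trends removed tested 9919 genes, without MIR744 and RNU6-28. The number of lists passing was 5 without a filter, 0 with an estimated correlation, 0 with fry, between 3 and 10 with a library or a pool left out, and 2 to 4 under the other settings. The replicate block gave 3 genes, without HBE1, and 3 lists. The DCK difference kept its sign and missed the threshold under every alternative, from -0.61 without pool 17 to -0.26 without resistant 28. The mean of the 3 correlations between pools was 0.201, and 0.168 to 0.315 under the alternatives run for it. Absolute depth was not estimated, so no limit set by depth was computed. No symbol stood in more than 1 place, so summing such values was not run.

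Some directions turned, in results that had not passed. LAT was 0.0496 with array weights, 0.06 without resistant 18 and 0.10 without pool 18, with -0.73 to 0.10 over the libraries and pools left out. ITGAM was -0.14, -0.19 and -0.18 under the same settings, with -0.19 to 0.70 over those left out. KRT18 was 0.15 without pool 18 (-1.17 to 0.15), and BMP2K was 0.0227 without pool 28 (-0.31 to 0.0227). The lists of S phase and of G2 and mitosis passed downward without resistant 18 (adjusted p = 0.00297 and 0.00403) and without pool 18 (0.0191 and 0.0175) at the preset correlation (0.872 with an estimated correlation over all 6 libraries), with adjusted p from 0.00297 to 0.844 and from 3.41e-04 to 0.803 over those left out.

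Other lists turned without passing. With no filter these were nucleotide breakdown (adjusted p = 0.740), T and NK (0.740) and myeloid markers (0.766); at a mean FPKM of at least 5, nucleoside uptake (0.960) and nucleotide breakdown (0.911); under quantile normalization both of these (0.987), ATF4 (0.987) and NF-kB (0.926); with the block, myeloid markers (0.995); with trends removed, nucleoside uptake (0.967), and with the block too, pro-apoptotic genes (0.991) and plasma cell (0.902). Without resistant 18 and without pool 18, p53 targets, DNA repair, ERK targets, plasma cell, NOTCH and cholesterol turned, as did myeloid markers without resistant 18 and MHC class II without pool 18. Without resistant 17 and without pool 17, nucleoside uptake, NF-kB and stromal markers turned, with plasma cell also without resistant 17 and nucleotide breakdown without pool 17. ATF4 turned without resistant 28 or pool 28, pro-apoptotic genes without resistant 28, MAPK without pool 28, nucleotide breakdown without control 17, plasma cell without control 18 and nucleoside uptake without control 28. Over the libraries and pools left out, adjusted p in either direction was 0.584 to 0.996 for nucleoside uptake and MAPK, 0.781 to 0.991 for nucleotide breakdown, 0.238 to 0.873 for p53, 0.0145 to 0.608 for DNA repair, 0.498 to 0.996 for pro-apoptotic genes, 0.0211 to 0.996 for ERK targets, 0.721 to 0.991 for plasma cell, 0.498 to 0.894 for NF-kB, 0.164 to 0.983 for MHC class II, 0.0782 to 0.883 for NOTCH, 0.157 to 0.996 for ATF4, 2.58e-04 to 0.772 for cholesterol, 0.623 to 0.996 for myeloid and 0.599 to 0.980 for stromal markers. Apart from the fewer genes tested without small RNA genes, the cause was not tested.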

Other observations

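Some genes in and beside the beta-globin cluster were lower in every resistant library than in every control. HBE1, at the cluster's end in the order of genes on GRCh38.p14, had 19.6, 26.0 and 26.3 FPKM in controls 17, 18 and 28 and 4.27, 3.23 and 2.44 in the resistant libraries. HBG2, a fetal globin gene beside it, had 2.06, 3.67 and 2.47 FPKM against 0, 0 and 0.655, and OR51B5, an olfactory receptor gene, 3.77, 3.02 and 3.53 against 0.608, 1.02 and 0.648. OR51B4 (0.717, 1.48 and 1.86 against 0.171, 0.164 and 0.0683) and HBD (0.572, 0.111 and 0.275 against 0) were near the floor. In these 5 of the 9 genes from HBB to OR51B6, each control was above each resistant library. Of these, HBE1, HBG2 and OR51B5 were among the 11307 tested genes, of which 11.1% were so separated, where chance gives 5%. The other 4, HBB, HBG1, OR51B2 and OR51B6, were listed at 0 in most libraries. The region was looked at because HBE1 had passed and OR51B5 and HBG2 had been named, so the count is no test of the region.

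The tests of DCK alone, of lower depth and of few fragments were chosen after the result was seen, as was the 41-gene window. The test of DCK alone by the length of the stretch replaced a bound of 75% on the share of the 41 genes below the median of all genes. It was replaced after the share was seen to be 75.6% in pool 18 and 92.7% in pool 28, and the exact 95% interval in pool 18, 59.7% to 87.6%, had not cleared the bound. Such an interval also takes neighbouring genes as independent, which they are not. The test by length was made stricter once the lengths had been seen, to ask also that no stretch between controls be as long. Before that it had counted against DCK alone in both pools, and after it, it could not tell.

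Genes on both sides of DCK had lower values in resistant 28, and those after it had in resistant 18, where 10 of the 20 before it were below the median of all genes. A trend with GC content or length does not account for this, since the median of the 41 genes was -0.78 in pool 28 and -0.30 in pool 18 as deposited, and -0.68 and -0.39 with the trends removed, among 8969 such windows at the 0.123 percentile both times in pool 28, and in pool 18 at 5.32 as deposited, where the lower region was centred on ANKRD17 to LIN54 and not on DCK, and at 0.714 with the trends removed. With the trends removed the lowest windows of all lay in this region in both pools (-0.71, centred on MTHFD2L and PARM1, in pool 28 and -0.57, centred on CCNI to MRPL1, in pool 18), against -0.20 to -0.37 for the lowest between controls. As deposited, the lowest window of pool 18 was -0.60, the median also of another region, MRPS2 to FBXW5. With the trends removed, DCK lay in a stretch of consecutive genes below the median of all genes. It had 24 genes in pool 28 and 25 in pool 18. One of 28 lay elsewhere between controls 28 and 18, so length decides nothing about a change of DCK alone. Values of the neighbours argue against a change confined to DCK in resistant 28 and resistant 18, in a region chosen after the data were seen. They do not show whether DCK also changed separately from its neighbours. Of the 20 genes after DCK, 20 were below that median in both pools (medians -0.60 in pool 28 and -0.73 in pool 18). Before DCK, 17 of the 20 were in pool 28 and 10 of the 20 in pool 18. A hypothesis is that resistant cells of pools 18 and 28 may have lost a copy of this region, or silenced it, which no DNA measurement analysed here tests. Other long regions also differed in these pools, such as KAT2A to PHB (0.43) in pool 18 and CD276 to AKAP13 (0.53) in pool 28.

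Resistant 18 stood apart from the other libraries. Lower depth does not account for it, as its relative depth of 1.09 was above that of 3 other libraries. RNA of T and NK, myeloid, erythroid, platelet, stromal or epithelial cells was not seen by their markers. Of 61 such genes, 4 (6.56%) were higher than in control 18 by over 1 on the log2 scale. VIM, the most abundant and also expressed in controls, had 424 FPKM in control 18 and 367 in resistant 18, and TRAT1 had 2.43 and 11.7. The markers cover no B cells, so they cannot tell whether RNA of other B cells was present. Its trend with GC content (Spearman -0.27 across genes) leaves the gene groups in place. Relative to all genes, G2 and mitosis genes had a median of 0.84 as deposited and 0.62 with the trends removed. Ribosomal protein genes had -1.02 and -0.91. With the trends removed, both lay outside the central 95% of 10000 random lists matched on mean expression. Those lists were drawn gene by gene, so that range does not allow for genes that move together (estimated correlations 0.908 and 0.594). For ribosomal protein genes the range was -0.83 to -0.16 as deposited and -0.51 to 0.11 with the trends removed. As deposited, part of their fall was thus shared by genes of like expression. In pool 18 as deposited, 29 of 30 G2 and mitosis genes and 30 of 32 S phase genes were above the median of all genes. MKI67 (-0.90), TYMS (-1.83) and CDT1 (-0.57) went the other way and were lower in resistant 18 than in control 18. A faster-growing culture at harvest, a different clone taking over the pool, or a difference in handling of this library may each be the cause, and none was tested.

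MIR744 and RNU6-28 were listed at 0 in every control. Times relative depth, the values of MIR744 were whole multiples of a step within 0.02 on the log2 scale, at most 5 steps in a library, which is consistent with a few fragments over a very short effective length. For RNU6-28 the value in resistant 28 was 3.09 steps, outside that tolerance, so a few fragments remain open for it. How often sampling of a few fragments sets 3 libraries apart from 3 among the 341 tested small RNA genes was not tested, so a higher level in resistant cells stays open.

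Other splits of the samples are too few to give a share under 0.05. The real split gave 4 genes, and the highest of the other 9 splits gave 9; 4 of the 10 splits, the real one included, gave at least as many. Of the 4 splits that part every pool, the other 3 gave 9, 1 and 1, and the split with 9 set resistant 18 with controls 17 and 28. At an unadjusted p under 0.05 the real split gave 1484 genes and the highest other 1338. With a library or a pool left out, the count between resistant and control libraries ran from 567 (without pool 28) to 2623 (without resistant 18).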
